A study of Arabidopsis thaliana with 9 samples.

How the data were processed

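The data were gene expression arrays of Arabidopsis thaliana pistils from ms1 (male sterile 1) plants of the Ler-0 ecotype. There were 9 arrays in 3 groups of 3 biological replicates: unpollinated pistils, pistils pollinated with wild-type Col-0 pollen, and pistils pollinated with pollen of a triple mutant in MYB97, MYB101 and MYB120. Pollinated pistils were left for 8 hours after pollination. Pistils were dissected and frozen, total RNA was extracted with a column kit, and the RNA was amplified and labelled with biotin with a 3' IVT express kit, per the labels. Every group was assigned from the sample titles.

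The deposited values were array intensity per probe set. The submitters' processing notes name RMA (background correction, normalization between arrays and summary of probes), the Affymetrix Expression Console and Partek, without versions. Log2 values had been assumed, but the deposited intensity values were linear, from 6.4 to 27175.1, so log2 was taken before every fit. The deposited values were powers of 2 whose exponent moved in steps of a hundredth of a unit, given to a single decimal. No detection calls and no scanner files were used, so a dim probe set cannot be called absent. The number of arrays limits the precision of every value.

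The table held 22810 probe sets, of which 64 control probe sets were left out and 22746 were tested. The platform annotation listed exactly 1 gene for 13513 probe sets, several genes for 503 and no gene for 8730. Of the probe sets with 1 gene, 13436 were matched to the reference annotation, which gave 13355 genes, and 1580 had a symbol other than a locus identifier. Gene names follow the TAIR10.1 assembly, and positions are not given, since the arrays measure transcripts. The probe sets without a listed gene were tested and counted but not named. The 3 mutated genes MYB97, MYB101 and MYB120 had no listed probe set, so their own transcripts could not be identified and the mutant labels were not checked against them.

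The log2 values of all 9 arrays were fitted with limma 3.58.1 in R 4.3.3 with 1 mean per group, which left 6 residual degrees of freedom beside 4.24 prior degrees of freedom. The 3 comparisons were wild-type pollen minus unpollinated, mutant pollen minus unpollinated, and mutant minus wild-type pollen. A probe set passed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Standard errors (SE) are those of the moderated limma fit and pool the spread of all 3 groups, also where the groups differ in spread. Replicate numbers were not used as a block in the fit. The arrays of the wild-type group enter both lists of the overlap between the rise with wild-type pollen and the fall with mutant pollen, and both changes from unpollinated pistils share the unpollinated arrays. The correlations that such sharing gives were therefore simulated 100 times with unchanged groups, and the overlap 20 times with mutant arrays equal to wild type. The fit was tested on simulated data, in which 200 of 22746 probe sets were changed. For wild-type pollen minus unpollinated it recovered 67.2% of changes of 0.5 on the log2 scale, 95.5% of changes of 1 and 100% of changes of 2, with 11 false calls. For mutant minus wild-type pollen it recovered 55.2%, 97% and 100%, with 6 false calls.

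The comparisons, 20 gene lists and the rule for named genes were fixed before the data were examined, and 17 gene families and functional classes were written after the data had been received but before any difference between groups was computed. The joined pollen tube lists combine signalling, cytoskeleton and secretion, wall and transport. A list gene with several probe sets was represented by the probe set with the highest mean, and 1 member whose symbol disagreed with the reference was left out. The ethylene list and the list of mutated MYB factors had 0 measured members. A member counted as measured where a probe set had it as the only listed gene. Coverage was low in many lists fixed before. It was 4 of 31 photosynthesis, 5 of 16 wall, 8 of 29 signalling, 4 of 15 cytoskeleton and secretion, 2 of 22 transport and 9 of 29 auxin genes. The joined pollen tube lists had 19 of 82 members measured, so list results describe the measured members alone. The lists planned from words in gene descriptions were left out, because the annotation had no descriptions. The 31 lists with at least 3 measured genes were tested in the 3 comparisons, 93 tests, with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 93 tests. Counts are given over all probe sets tested and, for lists fixed before, also adjusted over the list alone.

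The named genes followed that rule. For each comparison these were the 10 highest and the 10 lowest log2 differences among passing probe sets with 1 listed gene and no overlap between the groups, the 10 largest falls of the overlap, and up to 4 passing members of each list, or up to 2 as values where none passed. The mutated MYB genes were to be named always and could not be. HAT2 was named outside the rule, after its values were seen. What each named gene is known to do was given from general knowledge, not from the annotation.

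The amount of pollen tube RNA was compared between both pollinated groups by the mean of the joined pollen tube lists per array, with a two-sided exact permutation test whose smallest p with 3 arrays against 3 is 0.1. The alternatives tried were the replicate number as a block, a fit of the compared groups alone, dim probe sets left out below the 40th percentile, each array's median subtracted, a renewed quantile normalization, eBayes with trend and robust, stricter thresholds, subtraction of the shift of the pollen list, an estimated correlation, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 and tables handled with pandas 2.3.3 in Python 3.11.15.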

Results

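Transcript levels were measured on arrays in pistils of male sterile ms1 plants, which make no functional pollen of their own. The 9 arrays fell into 3 groups of 3: unpollinated pistils, pistils collected 8 hours after pollination with wild-type Col-0 pollen, and pistils collected 8 hours after pollination with myb97 myb101 myb120 triple mutant pollen. MYB97, MYB101 and MYB120 encode transcription factors of the pollen tube. Each array gave 22746 tested probe sets. Median intensities were 103.3, 104.7 and 103.3 in unpollinated pistils, 113, 112.2 and 117 with wild-type pollen, and 109.9, 114.6 and 111.4 with mutant pollen. The leading principal component held 85.2% of the variance and separated the unpollinated arrays, at -77.7 to -71.8, from the pollinated ones, at 31.8 to 40.1. Across probe sets, the array closest to mutant array 2 was wild-type array 1 (r = 0.9975), and the other mutant arrays were closest to a mutant array.

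The comparison of wild-type pollen with no pollination asked which transcripts changed in pistils that held growing pollen tubes, and the submitters aimed at tubes that had not yet reached the ovules. Among probe sets with 1 listed gene, several genes for enzymes that act on pectin were among the 10 highest rises after pollination. AT3G07820, a polygalacturonase, was 395-fold higher (log2 8.63 ± 0.19 SE, n = 3 per group), and the pectin methylesterase gene AT5G07430 was 230-fold higher (log2 7.85 ± 0.10). AT4G02250, a pectin methylesterase inhibitor-like gene, rose by a log2 of 7.86 ± 0.10, AT1G10770 of the same class by 7.42 ± 0.21, the pectate lyase gene AT3G01270 by 7.39 ± 0.14 and the polygalacturonase gene AT5G48140 by 7.02 ± 0.12. The other named genes among the 10 highest were AT5G39880 at 7.88 ± 0.15, AT3G28750 at 7.34 ± 0.23, the peroxidase gene AT5G47000 at 7.07 ± 0.11 and AT3G01240, which was 128-fold higher.

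Among probe sets with 1 listed gene, the lowest differences with wild-type pollen were those of AT2G33850 (36.9-fold lower, log2 -5.21 ± 0.18 SE, n = 3 per group) and of AT1G12010 (25.3-fold lower, log2 -4.66 ± 0.35), an ACC oxidase gene of ethylene synthesis. AT3G12000, which encodes an S-locus related glycoprotein, was 17.5-fold lower (log2 -4.13 ± 0.18). AT2G05540 for a glycine-rich protein had a log2 difference of -4.41 ± 0.37, AT1G33055 of -4.29 ± 0.17, AT4G27450 of -4.05 ± 0.36, AT1G16950 of -3.98 ± 0.17, AT4G19430 of -3.72 ± 0.26 and the peroxidase gene AT5G19880 of -3.71 ± 0.23. AT2G20560, a DnaJ family gene, had a log2 difference of -4.19 ± 0.63, with unpollinated arrays that spread widely at log2 levels of 6.63, 10.05 and 8.88.

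Most measured genes of growing pollen tubes rose in 3 of the lists fixed beforehand. All 5 measured pollen tube wall genes rose, with a median log2 difference of 4.25. Among them were AT5G45880, known as LAT52, at 6.64 ± 0.13 (99.8-fold), and the leucine-rich repeat extensin genes AT3G19020 at 4.67 ± 0.13 and AT1G49490 at 4.25 ± 0.15. Of 8 pollen tube signalling genes 6 rose, and 2 did not pass. The receptor kinase genes ANX2 and ANX1, needed to keep the pollen tube intact, rose by 5.23 ± 0.11 (37.5-fold) and 2.94 ± 0.13 (7.69-fold), and AT4G39110, known as BUPS1, rose by 4.42 ± 0.23. Of 4 cytoskeleton and secretion genes 3 rose, with PLIM2a at 5.24 ± 0.16 and the pollen actin gene ACT12 at 3.16 ± 0.09, while ACT11 fell by 0.71 ± 0.18. These 3 lists gave the same counts when adjusted over the list alone. Camera gave an adjusted p of 7.77e-07 for the wall list and 1.34e-05 for the signalling list. Both calls were lost with an estimated correlation (adjusted p = 0.459 and adjusted p = 0.461 with an estimated correlation), and the cytoskeleton list did not pass at 0.0549, or with an estimated correlation (adjusted p = 0.693 with an estimated correlation), but did when the lists fixed before were adjusted alone at the preset correlation (0.0383).

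The class of pollen pectin enzymes, written after the data had been received, had 13 of 15 measured genes higher and none lower, with a median log2 difference of 5.28 (camera adjusted p = 2.67e-13, and adjusted p = 0.459 with an estimated correlation). Of 5 pollen MIKC* MADS-box factors 3 rose, also when adjusted over the list alone, among them AGL104 by 0.92 ± 0.13 and AGL66 by 0.51 ± 0.07, and the list as a set did not pass (camera adjusted p = 0.129). The call of the other member, AGL65, was lost after renewed quantile normalization (adjusted p = 0.245). The sperm histone gene MGH3 rose by 0.98 ± 0.10, the 1 measured member of its list, also when adjusted over the list alone. Other genes that rose steeply in wider families were RALFL26 at 6.73 ± 0.19 and RALFL25 at 5.30 ± 0.11, which encode small secreted peptides, the serine carboxypeptidase-like gene scpl38 at 6.54 ± 0.10, the expansin gene EXPB5 at 4.37 ± 0.09 and LCR72, for a cysteine-rich peptide, at 4.35 ± 0.11.

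The few measured photosynthesis genes, 4 of 31 in the list, were lower after pollination with wild-type pollen. All 4 measured genes fell, also when adjusted over the list alone, with a median log2 difference of -0.71, among them LHCB4.2 at -1.24 ± 0.10 and RCA at -0.93 ± 0.09. The call of LHCB4.1 (-0.33 ± 0.11) was lost without unpollinated array 1 (adjusted p = 0.0931) or 2 (0.104) or wild-type array 1 (0.0524) or 3 (0.112), in a fit of the compared groups alone (0.0544) and after renewed quantile normalization (0.0808). Of 69 plastid-encoded genes 40 fell and 1 rose, with a median of -0.36, among them psbA at -1.68 ± 0.26 and rps15 at -1.26 ± 0.19. How evenly the 3' IVT labelling captured plastid transcripts was not checked. Camera gave an adjusted p of 0.014 for the photosynthesis list and 1.04e-06 for the plastid-encoded genes, and both were lost (adjusted p = 0.693 and adjusted p = 0.827 with an estimated correlation).

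Auxin genes moved in both directions with wild-type pollen. Of 9 measured, 4 rose and 1 fell, also when adjusted over the list alone. GH3.3, which encodes an enzyme that conjugates auxin to amino acids, was 50.5-fold higher (log2 5.66 ± 0.28), IAA30 rose by 0.98 ± 0.09, the auxin synthesis gene YUC6 rose by 0.85 ± 0.13, and WES1 of the GH3 family fell by 0.89 ± 0.12. The list median was 0.129 and changed sign when each array's median was subtracted (-0.00706), and the camera adjusted p was 0.522. WRKY53, a defence and senescence regulator in the touch and wound list, rose by 2.83 ± 0.20 (7.13-fold), and WRKY6 was the other of 3 measured members to pass (0.29 ± 0.10). The WRKY6 call was lost with array medians subtracted (adjusted p = 0.234), after renewed quantile normalization (0.662), with eBayes trend and robust (0.0545), and without unpollinated array 1, 2 or 3 or wild-type array 1 or 3 (0.0597 to 0.125). The transmitting tract regulator SPT rose by 0.71 ± 0.09, the only 1 of 5 carpel genes to pass, while 1 rose and 2 fell when adjusted over the list alone. The gibberellin receptor gene GID1A fell by 0.67 ± 0.13. Of 8 female gametophyte genes, the egg cell gene EC1.2 fell by 0.78 ± 0.17 and AGL80 rose by 0.53 ± 0.09. The touch and wound, gibberellin and female gametophyte counts did not change when adjusted over the list alone. Neither the carpel, touch and wound, gibberellin nor female gametophyte list passed as a set (camera adjusted p of 0.778, 0.352, 0.778 and 0.778). Of 6 stamen, petal and tapetum genes 3 rose, also when adjusted over the list alone, among them the extracellular lipase genes AT1G75880 at 1.35 ± 0.14 and AT1G75900 at 0.71 ± 0.17 (camera adjusted p = 0.388). The call of the remaining member, AT1G75890 (0.38 ± 0.12), was lost with array medians subtracted (adjusted p = 0.12), after renewed quantile normalization (0.357), and without unpollinated array 1 or 3 or wild-type array 2 or 3 (0.0637 to 0.12).

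Across the array, 5328 probe sets were higher and 4596 lower with wild-type pollen, which is 43.6% of those tested. A count not far from that share in a small list shows no response of the list. This holds for the auxin, MIKC*, touch and wound, and stamen, petal and tapetum counts above. Over all probe sets tested, 52.8% had no overlap between the groups, against 10% given by chance for 3 arrays against 3. By a log2 of at least 2, 434 were higher and 107 lower. The share of higher among passing probe sets was 53.7% as deposited, 32.2% (3607 higher, 7579 lower) when each array's median was subtracted and 43.5% (4510 higher, 5854 lower) after renewed quantile normalization. Subtracting the medians moved the median of all probe sets by -0.136, so the direction of small changes is relative to the scaling. The labels give 8 hours of growth for pollinated pistils alone and no collection time for unpollinated ones, so an effect of time was not separable from pollination.

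The comparison of mutant pollen with no pollination showed which of these changes took place with tubes that lack the 3 MYB factors. All 10 of the highest genes with wild-type pollen were among the 10 highest with mutant pollen, led by AT3G07820 at a log2 difference of 8.65 ± 0.19 (402-fold, n = 3 per group). Of the 10 lowest genes 9 were shared, led by AT2G33850 at -5.13 ± 0.18 (34.9-fold lower), and AT1G62510 of a lipid transfer family at -3.46 ± 0.15 took the place of AT4G27450. LAT52 (AT5G45880) rose by 6.50 ± 0.13, ANX2 by 4.97 ± 0.11, PLIM2a by 5.26 ± 0.16, GH3.3 by 5.57 ± 0.28 and MGH3 by 1.14 ± 0.10. Of the pollen lists, 5 of 5 wall genes, 7 of 8 signalling genes, 3 of 5 MIKC* factors (with AGL65 lost after renewed quantile normalization, adjusted p = 0.17) and 14 of 15 pectin enzymes rose. LHCB4.2 fell by 1.24 ± 0.10, RCA fell by 0.88 ± 0.09 and psbA fell by 2.03 ± 0.26.

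With mutant pollen, camera gave adjusted p values of 6.07e-07 for the wall list, 7.66e-06 for signalling, 9.23e-15 for pectin enzymes, 0.0143 for photosynthesis and 2.99e-09 for plastid-encoded genes. All of these calls were lost (adjusted p = 0.459, adjusted p = 0.461, adjusted p = 0.459, adjusted p = 0.693 and adjusted p = 0.815 with an estimated correlation). Adjusted over the list alone the wall, signalling and MIKC* counts stayed as above, and photosynthesis had 4 of 4 lower in place of 3 of 4. The joined pollen tube lists had 15 of 19 genes higher and 1 lower with wild-type pollen and 16 higher and 1 lower with mutant pollen (17 higher and 1 lower with mutant pollen when adjusted over the list alone). Their camera adjusted p was 1.82e-11 in both comparisons (adjusted p = 0.459 with an estimated correlation in both). In all, 5083 probe sets were higher and 4367 lower, 41.5% of those tested, and the limit on counts in small lists given for wild-type pollen holds here too. Over all probe sets tested, 50.5% had no overlap between the groups, against 10% given by chance. The share of higher was 53.8% as deposited, 35% (3578 higher, 6633 lower) with each array's median subtracted, a shift of -0.11 in the median of all probe sets, and 43.8% (4280 higher, 5496 lower) after renewed quantile normalization.

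The changes with both kinds of pollen ran closely together. Of the passing probe sets, 4522 were higher and 3863 lower in both comparisons, against 1191 and 882.4 for independent lists, and 1 had opposite calls (CYP78A9). The values for independent lists ignore the shared unpollinated arrays, and these joint counts were not simulated. Across probe sets, which are not independent replicates, the log2 differences correlated with Pearson's r = 0.9799. Unchanged groups that share the unpollinated arrays gave 0.5 on average in simulations and at most 0.525, and the covariance was 0.5339 against a simulated 0.00703. CYP78A9, a cytochrome P450 gene, rose by 0.49 ± 0.14 with wild-type pollen and fell by 0.40 ± 0.14 with mutant pollen. The call of its fall was lost without unpollinated array 1 (adjusted p = 0.0694) or 3 (0.0904) or mutant array 1 (0.107) or 3 (0.134) and in a fit of the compared groups alone (0.0732), and that of its rise after renewed quantile normalization (0.0653).

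**Figure D1:**
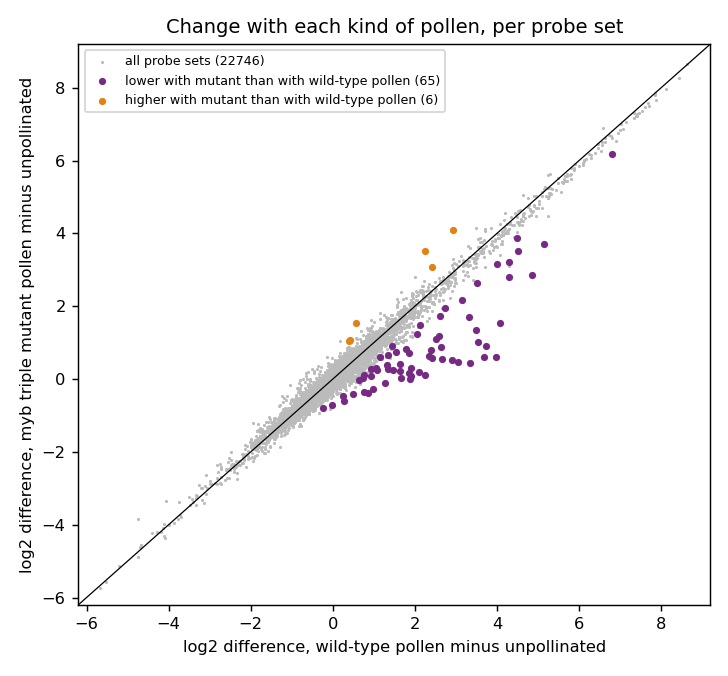
Log2 difference from unpollinated pistils for each of 22746 probe sets, with wild-type pollen on the horizontal axis and with mutant pollen on the vertical axis (3 arrays per group). Grey points follow the diagonal line of equal change (r = 0.9799), the 65 purple probe sets that were lower with mutant than with wild-type pollen lie under it, and the 6 orange ones that were higher lie above it.

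The comparison of mutant with wild-type pollen asked which transcripts of pollinated pistils differed when the pollen was mutant in MYB97, MYB101 and MYB120. RNA came from pistils together with the pollen tubes in them, so a rise or fall cannot be assigned to tube or pistil. The largest fall in a named gene was that of AT5G46200, which was 8.59-fold lower with mutant pollen (log2 -3.10 ± 0.27 SE, n = 3 per group, adjusted p = 0.000776). Its mean log2 level was 4.13 in unpollinated pistils, 7.82 with wild-type pollen and 4.72 with mutant pollen, where the 3 arrays were at 4.27, 5.54 and 4.35. The SD was 0.059, 0.174 and 0.71 in these groups, and the SE, which pools them, understates the spread of the mutant arrays. AT5G09280 for a pectin lyase-like protein was 7.49-fold lower (log2 -2.90 ± 0.29, adjusted p = 0.00144), and AT4G26830, a gene of the glycosyl hydrolase class that includes callose-degrading enzymes, was 5.83-fold lower (log2 -2.54 ± 0.26, adjusted p = 0.00172). The hexose transporter gene AT3G19940, known as STP10, was 5.26-fold lower (log2 -2.40 ± 0.22, adjusted p = 0.001), and the sugar transporter gene AT5G26250 of the same family was 3.11-fold lower (log2 -1.64 ± 0.11, adjusted p = 0.000157).

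The other genes among the 10 largest falls were AT3G26870, for a small secreted protein of the plant self-incompatibility S1 family, at -2.11 ± 0.13, AT1G06540 at -1.99 ± 0.23, AT1G02550 of the invertase and pectin methylesterase inhibitor family at -1.86 ± 0.16, IAA31 at -1.62 ± 0.22, and the subtilase gene AT1G66220 at -1.48 ± 0.18. Their adjusted p values ran from 6.07e-05 to 0.0124. IAA31 encodes an Aux/IAA protein of auxin response, and its call was lost without wild-type array 2 (adjusted p = 0.0608), mutant array 1 (0.0742) or mutant array 3 (0.0882). All 10 had risen with wild-type pollen, from 3.16-fold for AT5G26250 to 29.1-fold for AT1G06540. With mutant pollen, AT1G06540, AT1G66220, IAA31, AT4G26830 and AT3G26870 were still higher than in unpollinated pistils, by log2 differences of 2.87 ± 0.23, 2.81 ± 0.18, 1.69 ± 0.22, 1.53 ± 0.26 and 0.55 ± 0.13. The log2 differences of AT5G09280 (0.43 ± 0.29), AT1G02550 (0.005 ± 0.16) and AT5G26250 (0.02 ± 0.11) from unpollinated pistils did not pass. Those of AT5G46200 (0.59 ± 0.27) and AT3G19940 (0.51 ± 0.22) did not pass either, but passed without mutant array 1 (AT5G46200, adjusted p = 0.044), and with a replicate block or in a fit of the compared groups alone (AT3G19940, adjusted p = 0.0419 and adjusted p = 0.0371).

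**Figure D2:**
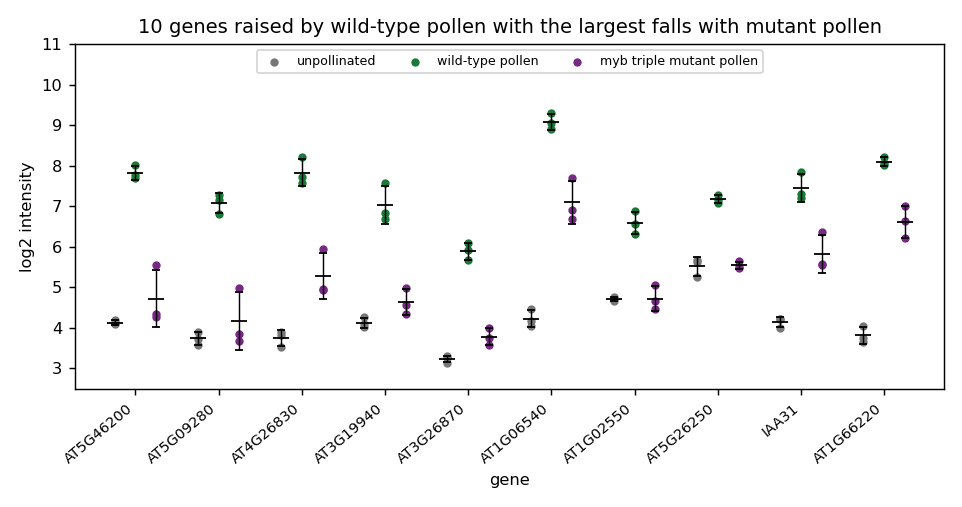
Log2 intensity of the 10 genes with the largest falls with mutant pollen among those raised by wild-type pollen. Each point is an array (3 per group), horizontal bars are group means and vertical bars are SD; for AT5G46200 the means were 4.13 in unpollinated pistils, 7.82 with wild-type pollen and 4.72 with mutant pollen.

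Few genes were higher with mutant pollen. AT3G11180, of the 2-oxoglutarate-dependent oxygenase class, was 2.38-fold higher (log2 1.25 ± 0.11, n = 3 per group, adjusted p = 0.000888), and AT5G66430, a methyltransferase family gene, was 1.97-fold higher (0.98 ± 0.10, adjusted p = 0.00181). The log2 differences were 0.67 ± 0.09 for AT2G11480, 0.66 ± 0.10 for AT1G73066 and 0.65 ± 0.10 for the papain-type protease gene AT4G23520 (adjusted p of 0.00923, 0.0178 and 0.0233). AT2G11480 and AT5G66430 were dim. Their mean log2 levels were 3.365 and 3.359 in unpollinated pistils, 3.75 and 3.925 with wild-type pollen, and 4.416 and 4.904 with mutant pollen. Calls were lost for AT2G11480 without wild-type array 1 (0.0547) or mutant array 3 (0.0675), for AT1G73066 without wild-type array 1 or 3 or any mutant array (0.0709 to 0.0896), and for AT4G23520 without wild-type array 1 or 2 or mutant array 1 or 3 (0.0849 to 0.152) and in a fit of the compared groups alone (0.0509). All 6 higher probe sets were also higher with either pollen than in unpollinated pistils.

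Of the lists, the transport list held STP10, 1 of its 2 measured genes, as its passing member, and 1 rose and 1 fell when adjusted over the list alone. Among 18 expansins EXPA16 fell by 0.88 ± 0.14 (adjusted p = 0.0341), after a rise with wild-type pollen of 2.60 ± 0.14, and this call was lost without any of the 6 pollinated arrays in turn (0.062 to 0.198). Among 23 cytochrome P450 genes CYP78A9 fell by 0.90 ± 0.14 (adjusted p = 0.0225), a call lost without wild-type array 1, 2 or 3 or mutant array 1 or 3 (0.0849 to 0.126), with a replicate block (0.0525) and in a fit of the compared groups alone (0.0527). No member of the wall, signalling, MIKC* or pectin enzyme lists passed between the pollens with limma, also over the list alone except for 2 pectin enzymes, and 0 of 5, 2 of 8, 0 of 5 and 3 of 15 had an unadjusted p under 0.05. The pectin enzyme gene AT3G06830 passed as higher with mutant pollen without wild-type array 3 (log2 0.737, limma adjusted p = 0.029). The joined pollen tube lists had a median log2 difference of -0.118 (-0.0325 without mutant array 1 and -0.197 without mutant array 2) and 1 of 19 genes lower, also when adjusted over the list alone (camera adjusted p = 0.0224, and adjusted p = 0.827 with an estimated correlation). Their mean log2 level per array was 7.53 with wild-type pollen (SD 0.0754), 7.33 with mutant pollen (SD 0.156) and 4.68 in unpollinated pistils, and the pollens were not separated by a two-sided exact permutation test (p = 0.2, smallest possible 0.1, n = 3 per group). Over all 434 probe sets raised 4-fold or more, a set chosen on the same wild-type arrays and so favouring a high wild-type mean, every mutant array lay below every wild-type array, with means of 8.16 (SD 0.147) and 8.39 (SD 0.0688) and a difference of -0.225 (exact p = 0.1, the smallest possible). Both sets hold STP10, and the 434 hold further probe sets that fell with mutant pollen. Both mean differences therefore contain part of the fall under study. The medians, -0.118 for the joined lists and -0.147 for the 434, rest less on such members. Plastid-encoded genes had a median of -0.107 with 0 of 69 passing in limma and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.00178, and adjusted p = 0.827 with an estimated correlation).

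In all, 65 probe sets were lower and 6 higher with mutant than with wild-type pollen. Over all probe sets tested, 9.96% had no overlap between the groups, against 10% given by chance. Of the 65, 37 were lower by a log2 of at least 1, and 26 had 1 listed gene, 9 several and 30 none. Of the 65, 61 (93.8%) belonged to the 5328 raised by wild-type pollen, of which they were 1.14%. Independent lists would give 15.2, but both lists share the wild-type arrays. In simulations of unchanged groups, that sharing alone gave a correlation of -0.5 across probe sets between the change with wild-type pollen and the difference of mutant from wild-type pollen, against -0.2857 observed. All variation in these simulations was noise, whereas the data hold large changes with pollination. The simulated correlation is therefore no measure of what sharing gave in the data, and no conclusion is drawn from it. With mutant arrays simulated as equal to wild type, 0.15 probe sets passed between the pollens on average (at most 2) and the overlap was 0, a count that so few calls all but fix. Of the 61 probe sets, 36 were still higher with mutant pollen than in unpollinated pistils, 24 did not pass and 1 was lower. The median probe set kept 28.4% of its log2 rise with mutant pollen. The 61 were chosen on these same arrays for a rise and a fall, which favours a low share kept. Mutant array 2 was the highest mutant array in 48 of the 61 probe sets and in 9 of the 10 largest falls of named genes. The median share kept was 45.1% in that array, 26% in mutant array 1 and 23.4% in mutant array 3. Mutant array 2 also had the highest mean log2 level of the joined pollen tube lists among mutant arrays. It was at 7.488, against 7.177 and 7.315 in mutant arrays 1 and 3, and 7.491, 7.488 and 7.62 with wild-type pollen. Whether pollen amount played a part in the share kept per array was not tested. Without mutant array 2 the overlap was 61, of which 50 were among the original 61. The overlap was 32 without mutant array 3, 33 without mutant array 1 or wild-type array 2, 39 without wild-type array 1, 41 without wild-type array 3 and 65 without unpollinated array 3, and 32 to 60 of the 61 probe sets were in it whichever of the 9 arrays was left out.

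**Figure D3:**
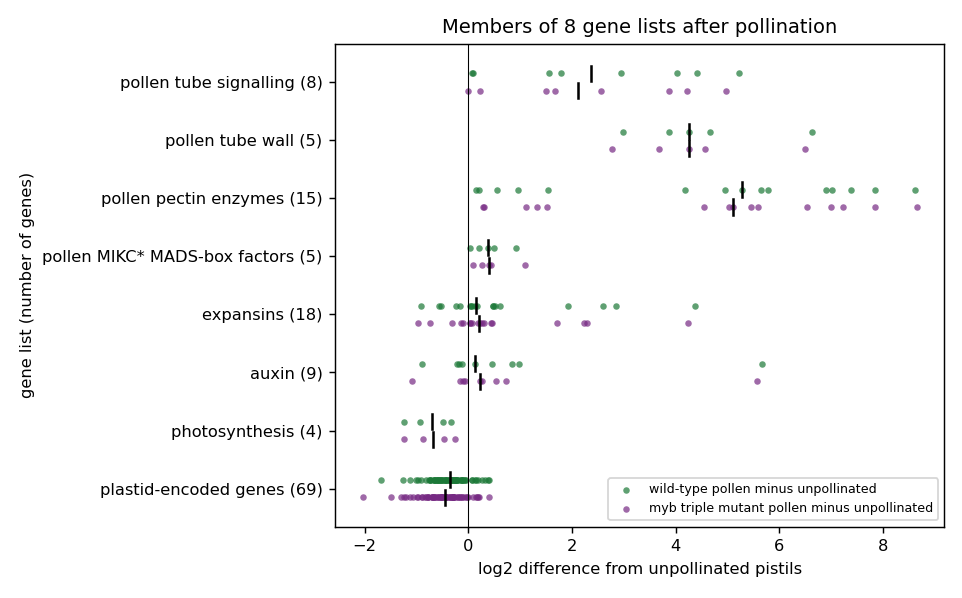
Log2 difference from unpollinated pistils for each measured member of 8 gene lists, with wild-type pollen (green) and mutant pollen (purple), black bars marking list medians. Pollen pectin enzymes (medians 5.28 and 5.1) and wall genes (4.25 and 4.26) lie far to the right and photosynthesis genes (-0.707 and -0.677) to the left; with wild-type pollen the auxin median changes sign when array medians are subtracted (-0.00706) and the expansin median after renewed quantile normalization (-0.00968).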

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

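The subtraction of the shift of all probe sets raised 4-fold and the count without the 17 later lists were added after the data were seen, and all other alternatives were fixed before. Named genes were rerun with the block, the separate fit, both scalings, eBayes with trend and robust and each array left out. In these, none of the 345 named gene values reversed, and 46 changed side of the threshold in some of them. Leaving out an array weakened 107 and strengthened 8 named gene values over all arrays, median subtraction weakened 19 and strengthened 5, renewed quantile normalization weakened 16 and strengthened 5, the fit of the compared groups alone weakened 10 and strengthened 3, the replicate block weakened 3 and strengthened 4, and eBayes with trend and robust weakened 2. With 3 arrays per group, precision was limited by the number of arrays. No detection calls were used, and a part played by signal over background was not tested.

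Median subtraction gave 7579 probe sets lower with wild-type pollen and 6633 lower with mutant pollen than unpollinated, in place of 4596 and 4367, with a shift of the median of all probe sets by -0.136 and -0.11, while the overlap was 59, of which 58 were among the original 61. An absolute log2 difference of at least 1 left 1025 higher and 625 lower with wild-type pollen, 922 and 587 with mutant pollen, 2 and 37 between the pollens, and an overlap of 34. An adjusted p under 0.01 left 2931 lower with wild-type pollen, 2776 lower with mutant pollen, 32 lower between the pollens, and an overlap of 32. These thresholds leave fewer probe sets by construction. Leaving out dim probe sets gave 3 higher and 35 lower between the pollens and an overlap of 34, all 34 among the original 61. Probe sets higher with mutant than wild-type pollen were 11 in a fit of those groups alone, 12 after subtraction of the pollen list shift of -0.118, and 14 after subtraction of the shift of all raised probe sets, which by construction moves every raised probe set up. The cause was not tested for the separate fit. In both subtractions 47 were lower and the overlap was 43.

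Of 93 list tests 14 passed with the preset correlation and 0 with an estimated correlation, at which 8 had an unadjusted p under 0.05, while fry passed 38 for a common direction and 63 for either direction. When the 42 tests on lists fixed before were adjusted alone, 11 passed. With the replicate number as a block, 5224 and 4488 probe sets were higher and lower with wild-type pollen, 4981 and 4302 with mutant pollen, 9 and 58 between the pollens, the overlap was 57 and 14 list tests passed. The array with the same replicate number was the closest in residuals in 4 of 9 checks. So few checks neither show nor exclude pairing by replicate number.

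With each array left out in turn, higher and lower counts ran from 4464 to 5344 and from 3527 to 4591 with wild-type pollen, from 4305 to 5007 and from 3521 to 4379 with mutant pollen, and from 3 to 16 and from 32 to 69 between the pollens. The count of 16 came without unpollinated array 3, and 3 without wild-type array 1 or mutant array 3. Lower counts between the pollens were 39, 33 and 42 without wild-type arrays 1, 2 and 3, and 33 and 32 without mutant arrays 1 and 3. The overlap ran from 32 to 65, the pollen list median from -0.197 to -0.0325, and the correlation between both changes from 0.9712, without mutant array 2, to 0.9814. The causes of these differences between arrays were not tested beyond the loss of an array.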

Other observations

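Apart from the splits for the overlap and for the counts between the pollens, the tests of causes below were chosen after the results were seen, and those of a deviating array and of dilution replaced earlier tests whose outcome was known. Several wider gene families held members that moved strongly with wild-type pollen, in either direction. Of 47 UDP-glycosyltransferases 15 rose and 6 fell, and UGT76B1, which acts on defence-related small molecules, was 4.08-fold higher (log2 2.03 ± 0.16 SE, n = 3 per group) and UGT87A2 3.86-fold higher (1.95 ± 0.09). Of 20 beta-glucosidases 7 rose and 5 fell, and BGLU45 and BGLU46, linked to lignin precursors, had log2 differences of -2.73 ± 0.14 and -2.22 ± 0.09 while BGLU36 rose by 2.65 ± 0.24. Among 23 cytochrome P450 genes 2 rose and 4 fell, with CYP71B23 at 2.60 ± 0.13 and CYP79A2 at -1.45 ± 0.13. Of 15 tetraspanins 4 rose and 6 fell, with TET13 at 2.81 ± 0.13. Of 18 expansins 7 rose and 2 fell, with EXPA4 at 2.85 ± 0.14 and EXLA3 at 1.92 ± 0.13. Of 6 cation/H+ exchangers 5 rose, among them CHX6B at 1.41 ± 0.09, while the call of CHX19 was lost with either rescaling (adjusted p = 0.055 and 0.119) and without unpollinated array 1 or 2 or any wild-type array (0.0504 to 0.0803). Counts by family rest on the deposited scaling. Over all probe sets tested 43.6% passed with wild-type pollen, so a family count near that share, here or in the next paragraph, shows no response of the family. The medians of the glycosyltransferase and beta-glucosidase families, 0.097 and 0.0136, changed sign when array medians were subtracted (-0.0393 and -0.123), and none of these families passed as a set (camera adjusted p from 0.052 to 0.826).

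Sugar transporters of the SWEET family moved apart, with 4 of 14 higher and 3 lower with wild-type pollen, SWEET8 at 1.05 ± 0.22, SWEET13 at 0.95 ± 0.19, SWEET11 at -1.04 ± 0.13 and SWEET10 at -0.78 ± 0.11. Of 10 NET actin-binding proteins 3 rose and 1 fell, with NET2C at 1.49 ± 0.11 and NET3A at -0.78 ± 0.11, while the call of NET1A was lost with either rescaling (adjusted p = 0.135 and 0.0657), in a fit of the compared groups alone (0.0753) and without unpollinated array 1 or 2 or wild-type array 1 or 3 (0.12 to 0.163). Of 9 xyloglucan endotransglucosylase/hydrolases 3 rose and 1 fell, with XTH32 at 1.02 ± 0.17. The calls of XTH18 and XTH33 were lost without wild-type array 2 (adjusted p = 0.0506 and 0.0613), that of XTH33 also without wild-type array 3 (0.0577) and that of XTH18 with array medians subtracted (0.057). Of 40 AGAMOUS-like factors 8 rose and 5 fell, with AGL16 at -0.83 ± 0.07, of 22 trichome birefringence-like genes 5 rose and 3 fell, with TBL38 at -0.95 ± 0.13, of 29 serine carboxypeptidase-like genes 6 rose and 4 fell, with SCPL49 at 0.98 ± 0.07, of 15 defensin-like genes 5 rose and 2 fell, with LCR59 at -0.58 ± 0.15, of 10 RALF-like genes 2 rose and 1 fell, with RALFL32 at -0.37 ± 0.10, and of 8 glutamate receptor-like channels 1 rose, GLR3.5, whose call was lost with either rescaling (adjusted p = 0.0618 and 0.297). In the smaller lists, 1 of 2 jasmonate and 2 of 3 cell cycle genes passed with small rises. The jasmonate gene PDF1.2 lost its call with array medians subtracted (adjusted p = 0.0669) and after renewed quantile normalization (0.331). Both cell cycle calls were lost with array medians subtracted (AUR2, 0.0972, and PRL, 0.14) and without wild-type array 3 (0.0509 and 0.082), and that of PRL also without unpollinated array 1 or 2 or wild-type array 2 (0.0899 to 0.105). None of 4 senescence genes passed, among them AT2G14095 at -0.99 ± 0.37, which passed without unpollinated array 3 (adjusted p = 9.36e-06) and with the replicate block (0.0281), and SAG29 at -0.55 ± 0.22, which passed without wild-type array 3 (0.0211). For both, median subtraction and renewed quantile normalization also gave passing values (0.0191 to 0.0413). Neither the salicylate gene GRX480 (-0.90 ± 0.40) nor the heat shock gene ATHSP22.0 (-0.02 ± 0.13) passed, with limma adjusted p of 0.0915 and 0.915 for these 2, although GRX480 passed when adjusted over the list alone, without unpollinated array 1 (adjusted p = 0.00508), with array medians subtracted (0.048) and after renewed quantile normalization (0.0485). With wild-type pollen, the jasmonate, senescence and cell cycle counts did not change when adjusted over the list alone. None of the tested lists of this paragraph passed as a set (camera adjusted p from 0.46 to 0.932). With wild-type pollen, the RALF-like and NET lists had a median below 0 (-0.0933 and -0.103) beside a mean (1.07 and 0.121) and a camera direction above 0, the tetraspanins a median of -0.185 beside a mean of 0.0881, and the trichome birefringence-like genes a median of 0.0116, which changed sign with array medians subtracted (-0.125) and after renewed quantile normalization (-0.071), beside a downward camera direction.

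The pattern followed up here is the overlap of 61 probe sets raised by wild-type pollen and lower with mutant pollen. If pistils given mutant pollen only held less pollen tube RNA, all probe sets raised by that RNA would fall alike. Of the 61, 43 stayed lower after the median difference of the 434 raised 4-fold or more (-0.147) was subtracted. These 43 fell by more than the common shift, which argues against this as the whole cause for them. The count itself carries little weight, since the 61 were chosen for their falls (median -1.25). The 434 may also hold pistil transcripts, and a single shift ignores that pollen tube list levels differed between mutant arrays. A single deviating array is argued against as well, since at least 32 probe sets were in the overlap whichever of the 9 arrays was left out. The splits of the arrays were too few for a share under 0.05: for the overlap the real split of the 6 pollinated arrays gave 61 and the highest of the other splits 0, and 1 of the 10 splits gave as many. What stays open is a part played by a small difference in pollen tube RNA, and the loss of the MYB factors, which the design names, stays open as a hypothesis beside other differences between the pollen donors.

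The same limit holds for the counts of passing probe sets: the real splits gave 9924 with wild-type pollen, 9450 with mutant pollen and 71 between the pollens, the highest of the other splits gave 0, and 1 of the 10 splits in each case gave as many, which is too few splits for a share under 0.05.

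The next pattern is the fall of pistil transcripts after pollination. If RNA of pollen tubes diluted pistil RNA, genes that pollen tubes lack would fall alike. Among the 107 probe sets that fell by a log2 of 2 or more, dilution is argued against as the whole cause, since 60 of the 61 photosynthesis and plastid-encoded genes with an unpollinated log2 level of at least 8 fell short of that by over 2 SE, psbA (-1.68 ± 0.26) being the exception. All but the 4 measured photosynthesis genes among these 61 were plastid-encoded. How evenly the 3' IVT labelling captured plastid transcripts was not checked. The largest fall among those 4 genes was -1.24 ± 0.10, also short of a log2 of 2, so the evidence apart from plastid transcripts rests on 4 genes. For the 4489 probe sets that fell by less, the median was -0.476, between the plastid-encoded median of -0.36 and the photosynthesis median of -0.707. These probe sets were chosen for smaller falls, and lower expression in the pistil would allow this median too. The 4 measured photosynthesis genes did not fall alike, from -1.24 for LHCB4.2 to -0.33 for LHCB4.1. So few genes do not settle the cause for the 4489 probe sets. Dilution and lower expression in the pistil therefore cannot be told apart for these probe sets. The time since pollination and the other ecotype of the pollen are not separated from pollination by the design.

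The last pattern concerns auxin. HAT2, a homeodomain-leucine zipper gene induced by auxin and chosen after its values were seen, was 2.67-fold lower with mutant than with wild-type pollen (log2 -1.42 ± 0.21, adjusted p = 0.0193), a call lost without wild-type array 1, 2 or 3 or mutant array 3 (0.0897 to 0.125), and IAA31 was 3.08-fold lower. A wider auxin response in pistils with wild-type pollen may underlie this. The auxin list, which holds neither gene, had a median difference of -0.09 between the pollens with 0 of 9 genes passing in limma and 2 at an unadjusted p under 0.05, and its camera p was 0.0887. GH3.3, the member with the largest rise, had log2 levels of 10.69, 10.63 and 10.33 with wild-type pollen and 10.75, 10.36 and 10.27 with mutant pollen. A single member does not settle a wider response, so the hypothesis stays open.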
